A study of Homo sapiens with 2 samples.

How the data were processed

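KDM2B occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in OCI-Ly1, an established cell line of diffuse large B cell lymphoma. Per the labels, the series holds 2 libraries, a KDM2B immunoprecipitate made with an affinity-purified rabbit polyclonal antibody and an input library of the same line. The libraries were made with Illumina ChIP-seq kits, per the labels' protocols. Each library was the only one of its group. The values analysed here come from 1 peak list, that of the KDM2B library. Signal of the input library was not analysed here.

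The peak list has no header, and the meaning of its 11 columns was worked out from the values. Its name carries the peak caller ChIPseeqer and the tags T15 and F2. The genome build is hg18, per the submitters' processing notes. The aligner, the read filters and the way the input entered the calling are not given in the sources used here. Chromosome, start and end are printed as the authors' list gives them. The deposited width equals end minus start in all 26471 peaks, the midpoint is the rounded-down mean of start and end in all 26471, and the summit lies inside the peak in all 26471. The authors' percent column equals the position of the summit along the peak, within 0.05 percentage points in every row.

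One deposited score column was read as the average log10 of a p-value over the peak, since its finite values run from -148 to -15.0 and stop at the 15 in the tag. It is minus infinity in 9 peaks, which were kept and left out of its median. The second deposited score column is positive, and its formula is not given in the sources used here. It is called the peak score below. The deposited signal is a whole-number height at the summit, taken as the number of reads stacked there. No scaling of it is stated. The total read number of the libraries is unknown, so no height could be set against sequencing depth.

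The list was summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Medians carry 95% intervals from order statistics, shares carry exact Clopper-Pearson 95% intervals, and peak densities carry exact Poisson 95% intervals. These intervals cover counting error over peaks of 1 library, not the spread between cultures. They take peaks as independent, which grouped peaks are not, so they can be too narrow. With 1 library per group no test between conditions was possible. Peaks of 1 list are not independent replicates, so relations across peaks are given as coefficients with bootstrap 95% intervals from 1000 resamples.

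Peak density was the number of peaks per Mb between the first and the last peak of a chromosome, unsequenced stretches included. Chromosome Y was left out of the values given by chromosome. Peaks were counted in 1 Mb windows by their midpoint. The fullest window was compared with the fullest one after the gaps between midpoints had been put in random order within each chromosome, in 1000 permutations. Peaks less than 1 kb apart were merged into regions. Peaks just past the threshold were those with an average log10 p from -17 to -15. For the 1 relation across chromosomes, which was not planned, Pearson and Spearman coefficients were tested with 100000 two-sided permutations.

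Segments of low peak height were sought after the data had been seen. Every second peak was used, in 10 Mb windows with at least 5 such peaks. A window was low where its upper-quartile height was below 0.75 of that of the chromosome, and a segment was a run of at least 2 low windows. Values inside segments come from the other peaks, except those of peaks just past the threshold, which use every peak. The score at a given height was taken from a linear fit of log2 score on log2 height, its square, log2 width, the summit's position in percent and its distance from the midpoint, over the peaks outside the segments of the same chromosome.

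Both procedures were tested on simulated data of 26471 peaks per list, before any were planted. With gaps in random order, 1 of 20 lists gave a p under 0.05, and a window with 200 planted peaks was found in 10 of 10 lists. The lists in random order were made by the same shuffling as the test, so they check only how it was carried out. The 200 planted peaks exceed the 154 of the fullest observed window, so the power to find less full windows was not measured. With heights shuffled within chromosomes, 1 segment was called over 20 lists, and a 30 Mb segment with heights scaled by 0.6 was found in 18 of 20 lists.

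Chosen before the data were examined were the peaks named in the text, which are the 10 tallest, the 10 highest-scoring and the 5 widest, and the 5 fullest 1 Mb windows. So were the alternatives, except a uniform minimum height of 60 and those on chromosome ends, which were chosen after seeing the data. Promoter overlap, CpG content and fixed gene lists had been planned for the case that an annotation of hg18 was at hand. The gene table used here is of GRCh38, coordinates were not converted between builds, and so no peak was assigned to a gene.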

Results

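The series concerns a Polycomb complex with BCOR in germinal center B cells and lymphoma, and this part of it located KDM2B in OCI-Ly1 lymphoma cells. KDM2B is a histone demethylase whose CXXC zinc finger binds unmethylated CpG, and it is the subunit that brings the BCOR-containing PRC1.1 complex to CpG islands. The data were 1 list of 26471 KDM2B peaks on 24 chromosomes of hg18. There was 1 immunoprecipitated library without a replicate, so every value describes that library. The depth of the library is unknown.

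The peaks covered 12.9 Mb in all. The median peak was 326 bp wide (95% interval 321 to 331), with quartiles of 180 and 639 bp and a range of 99 to 6356 bp. With peaks less than 1 kb apart merged, the median width was 569 bp. Peaks wider than 1000 bp made up 11.5% of the list (3031 of 26471, 95% interval 11.1 to 11.8%), and peaks wider than 2000 bp made up 1.44% (380 peaks, 1.30 to 1.59%). The median height at the summit was 71, with quartiles of 56 and 94 and a range of 26 to 327. The median peak score was 40.1 (95% interval 39.96 to 40.33), and the highest was 159. In 65.2% of peaks the summit lay in the central 40% of the peak (17246 peaks, 64.6 to 65.7%).

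**Figure D1:**
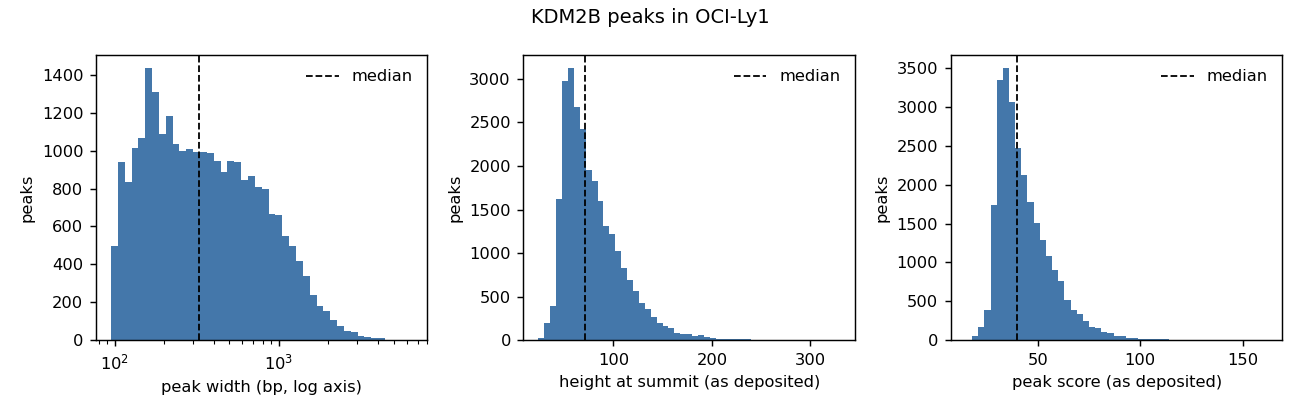
Histograms of width in bp on a log axis, summit height and peak score over the 26471 KDM2B peaks of 1 library, with dashed lines at the medians of 326 bp, 71 and 40.1. Each distribution has a long right tail, up to 6356 bp, 327 and 159.

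Wide KDM2B peaks were also tall. In the narrowest 25% of peaks, up to 180 bp, the median height was 52 (95% interval 52 to 53) and the median score 32.2 (32.1 to 32.3). In the widest 25%, from 639 bp, the median height was 106 (105 to 107) and the median score 54.9 (54.5 to 55.3). Across all peaks, Spearman's rho was 0.80 between width and height (bootstrap 95% interval 0.79 to 0.80; Pearson's r of log2 values 0.79). It was 0.76 between width and score (0.76 to 0.77; r 0.75) and 0.93 between height and score (0.93 to 0.93; r 0.94). These coefficients are across peaks of 1 library, which are not independent replicates. Width, height and score describe the same called peak, so part of each relation may come from how peaks are called, which was not tested. Among the 25% of peaks with the highest scores the rho of width and height was 0.47 and that of width and score 0.35.

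The tallest peak of the list was also the highest-scoring one. It spanned chromosome 11 from 109671585 to 109673570, with a height of 327 and a score of 159. Next in score were a peak on chromosome 12 from 92487608 to 92490516, with a height of 294 and a score of 158, and a peak on chromosome 3 from 135451045 to 135452770, with a height of 291 and a score of 152. With a peak on chromosome 15 from 72625203 to 72626235 (height 282, score 138), these were the 4 peaks that stood among both the 10 tallest and the 10 highest-scoring. The average log10 p was minus infinity in 8 of the 10 tallest peaks and in 9 peaks of the whole list. The lowest height among those 9 was 259, and 16 peaks reached that height.

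Other tall peaks ranked lower by score. The second tallest, on chromosome 3 from 188027699 to 188028419, had a height of 296 and ranked 22 by score. The peak on chromosome 1 from 143750622 to 143752035 had a height of 293, the fourth highest, and a score of 97.5, which ranked 117. A peak on chromosome 16 from 3139538 to 3141068 had a height of 283 and ranked 11 by score, and one on chromosome 7 from 20335845 to 20338379 had a height of 276 and ranked 71. On chromosome 10, both the peak from 163780 to 164219 and the peak from 170165 to 172777 were among the 10 tallest, with heights of 266 and 278. They lay 5946 bp apart near the first called position of the chromosome.

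Some of the highest-scoring peaks were neighbours. On chromosome 7 the peaks from 127457686 to 127458949 (score 147) and from 127459077 to 127460463 (score 141) were separated by 128 bp, and their summits lay 468 bp apart. The summits faced each other, at 86.1% of the length of the first peak and 11.9% of the second. On chromosome 5 the peaks from 42984967 to 42986014 (score 140) and from 42986259 to 42988545 (score 139) were separated by 245 bp. Their summits lay 1774 bp apart. Whether either pair was a single site split by the peak caller was not tested. The remaining highest-scoring peaks lay on chromosome 17 from 73424043 to 73425087 and on chromosome 7 from 104815331 to 104816604, both with a score of 136.

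The widest peak ranked 2125 by height. It spanned 6356 bp of chromosome 2, from 111591067 to 111597423, with a height of 124 and a score of 55.9. The second widest, on chromosome 13 from 113911862 to 113916662, had a height of 225. The peaks on chromosome 9 from 101622954 to 101627485 and on chromosome 8 from 134650230 to 134654656 had heights of 202 and 194. The fifth widest, on chromosome 3 from 198233410 to 198237813, had a height of 140, with its summit at 95.6% of its length.

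The called KDM2B peaks came in groups. The gap from one peak to the next was under 1000 bp in 29.6% of cases (7831 of 26447 gaps, 95% interval 29.1 to 30.2%), and it was 10 kb or more in 54.0% (53.4 to 54.6%). On a log scale the gaps formed 2 modes, one from 158 to 251 bp with 2291 gaps and one from 39.8 to 63.1 kb with 2126 gaps. The bin between them with the fewest gaps, from 1000 to 1585 bp, held 640. No gap was shorter than 101 bp. The mode of short gaps lay close to that minimum, and a broad site split by the peak caller could also give short gaps. How much of the grouping came from such splitting was not tested. Merging peaks less than 1 kb apart left 18640 regions, of which 5501 held more than 1 peak. Those regions held 13332 peaks, 50.4% of the list. Peaks in them had a median height of 71 (95% interval 71 to 72), against 70 (70 to 71) for single peaks.

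**Figure D2:**
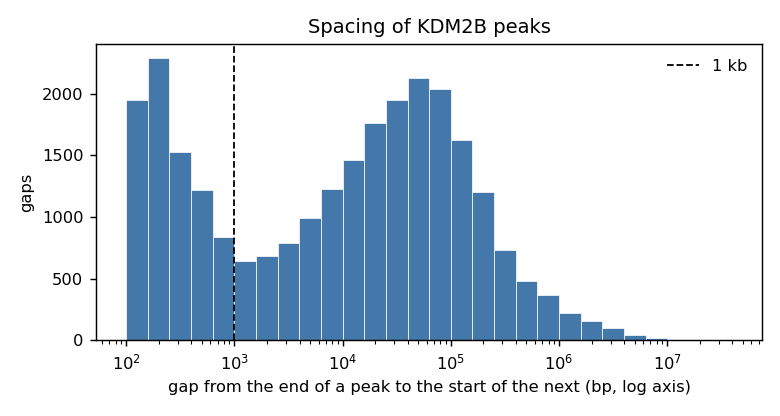
Number of gaps between neighbouring KDM2B peaks by gap length in bp (log axis), with a dashed line at 1 kb. The modes lie from 158 to 251 bp and from 39.8 to 63.1 kb, and 29.6% of the 26447 gaps are under 1000 bp.

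The region that was both widest and held the most peaks lay near the end of chromosome 18, from 75254059 to 75267178. It was 13.1 kb long and held 12 peaks, the tallest with a height of 168. The next widest were a region of 11.8 kb with 7 peaks on the X chromosome, from 39834185 to 39846000, and a region of 9.87 kb with 6 peaks on chromosome 17, from 77779401 to 77789270. These regions fall outside the rule for named peaks and were chosen after their values were seen.

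KDM2B peak density varied over the chromosomes. It was highest on chromosome 19, with 17.5 peaks per Mb (95% interval 16.5 to 18.5), and on chromosome 17, with 17.0 (16.12 to 17.96). It was lowest on the X chromosome, with 4.61 (4.27 to 4.97), and on chromosome 4, with 5.35 (5.03 to 5.69). Chromosome 21 had 13.4 (12.2 to 14.7), and chromosome 18 had 6.86 (6.28 to 7.48). The density on chromosome 19 was 3.26 times that on chromosome 4 (95% interval 2.997 to 3.552). Because peaks came in groups, these intervals are likely too narrow.

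Peak height varied by chromosome too. The median was highest on chromosome 11, at 92 (95% interval 88 to 95), and on chromosome 7, at 85 (82 to 88). It was 57 (55 to 59) on chromosome 4 and 41 (40 to 42) on the X chromosome. The X median was 0.569 of the median of the 22 autosomal values, which was 72. The lowest height that was called differed between chromosomes as well. Peaks just past the threshold had a median height of 31 on the X chromosome and of 38 on chromosome 4, and of 55 on chromosome 22. These peaks are part of the same list, so the median height and the height at the threshold are not independent. Across the 23 chromosomes, the height at the threshold was higher where peaks were denser (r = 0.71, permutation p = 9e-05; rho = 0.66, permutation p = 0.0009). Without chromosomes 22 and X, r was 0.63. The relation was not planned, and the density and the height at the threshold come from the same called peaks. Its p-values are therefore descriptive and not independent evidence. Counting only peaks of height 60 or more, chromosome 19 held 14.4 peaks per Mb, chromosome 4 held 2.46 and the X chromosome 0.664, and the ratio of chromosome 19 to chromosome 4 became 5.84.

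**Figure D3:**
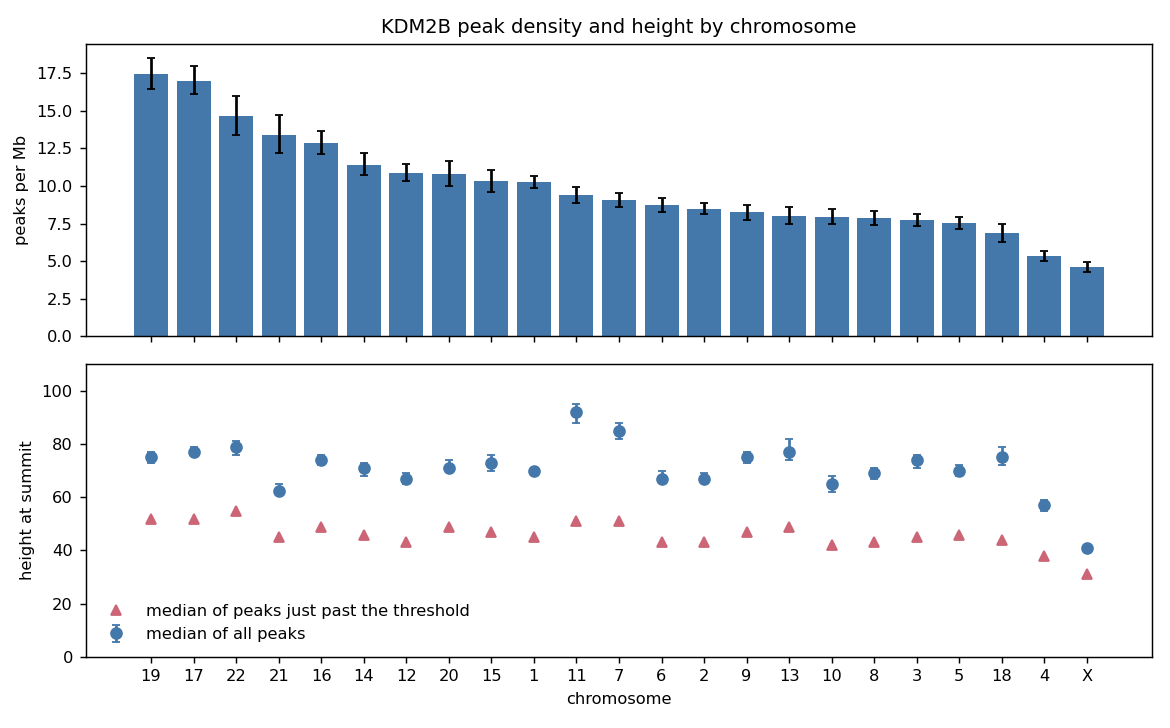
Top, KDM2B peaks per Mb by chromosome with exact Poisson 95% intervals; bottom, the median summit height of all peaks with its 95% interval (circles) and of the peaks just past the threshold (triangles). Chromosome 19 has the most peaks per Mb (17.5) and the X chromosome the fewest (4.61), and the X chromosome also has the lowest median height (41) and height at the threshold (31).

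Some 1 Mb windows were unusually full of KDM2B peaks. The median of the 2169 windows with a peak was 8 peaks. The fullest window, on chromosome 14 from 104 to 105 Mb, held 154 peaks, 13.5 times the mean of its chromosome, with a median height of 69 (95% interval 63 to 77). With the gaps in random order the fullest window held a median of 53 peaks and at most 82, so that the observed count was above all 1000 permutations (permutation p = 0.001, one-sided, the smallest they can give). In 28 windows the count was above 64, the 95th percentile of the permuted maximum. The next fullest were 2 windows on chromosome 8, from 142 to 143 Mb with 117 peaks and from 145 to 146 Mb with 105 peaks. The first Mb of chromosome 11 held 104 peaks, and chromosome 13 from 112 to 113 Mb held 102. Median heights in these 4 windows were 59, 86, 79.5 and 60.5. Of the 15 fullest windows, 14 began within 5 Mb of the first position or the last peak of their chromosome.

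Peak height was not even along some chromosomes. Segments of low height, sought after the data had been seen, were found on 3 chromosomes. In the first 30 Mb of chromosome 4 the median height was 46 (105 peaks), against 62 in the rest of the chromosome (406 peaks). In the first 30 Mb of chromosome 8 it was 52 (61 peaks) against 71 (508 peaks). On chromosome 10 from 110 Mb to the last peak it was 54 (55 peaks) against 68 (483 peaks). The segments were chosen for low heights in the peaks that these values leave out. Since 50.4% of peaks lay in regions of several peaks, both sets can share sites and are not independent. The 90th percentile of height was 63 against 114 on chromosome 4, 69 against 131 on chromosome 8, and 68.6 against 116 on chromosome 10. The shuffled lists gave 1 such segment in 20 lists. Shuffling single peaks removed any likeness in height between neighbours, so it does not show how often clustered peaks would give such segments. The segment boundaries are those of 10 Mb windows, and a call needed at least 2 low windows, so shorter segments could not be called. The rule can also miss low stretches. In the last 20 Mb of chromosome 11 (71 peaks), which was not called, upper-quartile height was 0.567 of that in the rest of the chromosome.

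**Figure D4:**
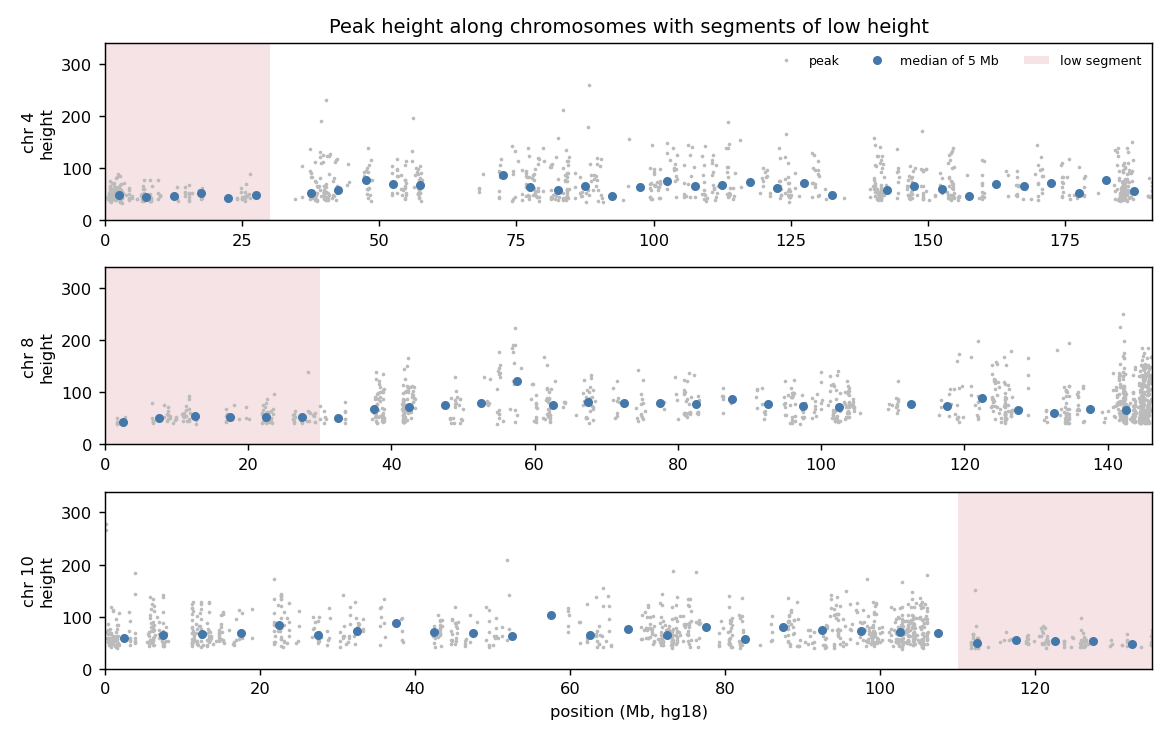
Summit height of each KDM2B peak (grey) and the median of each 5 Mb window with at least 5 peaks (blue) along chromosomes 4, 8 and 10, against position in Mb of hg18. Shaded segments are those of low height, where the median heights were 46, 52 and 54, against 62, 71 and 68 elsewhere on the same chromosomes.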

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

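The uniform minimum height of 60 was chosen after seeing the data, as were all settings on chromosome ends; the others were planned. Of the 26471 peaks, 13236 scored at or above the median and 6618 were in the top 25% by score, by construction. Median width was 599 bp above the median score, 813 bp in the top 25% and 569 bp after merging peaks less than 1 kb apart. Median height was 94 above the median score, 113 in the top 25%, 77 after merging (the tallest of each region) and 72 on autosomes alone. Median score was 50.3, 58.9, 42.5 and 40.5 under the same settings. In the top 25% by score, Spearman's rho fell to 0.47 for width and height, 0.35 for width and score and 0.76 for height and score. Without the highest and lowest 1% of widths it was 0.79, 0.75 and 0.93. All 3 relations stayed positive. The top 25% was cut on score, which was itself related to width and height, and such a cut can lower the coefficients. The drop therefore does not show that high-scoring peaks behave otherwise, and any further cause was not tested. The density ratio of chromosome 19 to chromosome 4 was 5.84 for peaks of height 60 or more, since that minimum removed more of the lower peaks of chromosome 4, and it was 3.27 after merging and 3.33 in the top 25%. The fullest window stayed above all 1000 permutations with 250 kb windows (65 peaks), 5 Mb windows (293), merged peaks (88), the top 25% by score (43) and heights of 60 or more (99). A minimum fold over input could not be tried, since the list holds no fold, and the alternatives on promoters, gene lists and CpG content were not run. No paired analysis was possible because each group holds 1 library. The unknown depth and the lack of a replicate limit every value: sites under the authors' threshold were not listed, and their absence does not show that KDM2B was absent.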

Other observations

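The tests of explanations on segments and on the height at the threshold were chosen after the results were seen; the bounds of the tests on chromosome ends were written before their results, after the fullest windows had been seen. KDM2B peaks were dense next to the chromosome ends. In the 5 Mb next to the outermost peaks there were 27.1 peaks per Mb (5550 peaks), against 7.70 elsewhere (20896 peaks). The median ratio over 23 chromosomes was 2.62, and the density was higher at the ends on 22 of them (two-sided sign-flip permutation p = 1e-05, the smallest 100000 draws can give). The fullest windows had been seen before this comparison, and it used the same peaks. Its p therefore does not test the pattern in new data. The ratio was highest on chromosome 21, at 11.97, followed by chromosome 13 at 8.74, chromosome 8 at 7.06 and chromosome 16 at 6.85. Chromosome 15, at 0.988, was the exception. On chromosomes 13, 14, 15, 21 and 22, where no peak lay in the first 5 Mb, only the far end was counted. Pooled over chromosomes, peaks at the ends were slightly lower than the others, with a median height of 68 (95% interval 67 to 68) against 72 (72 to 73), and narrower, with a median width of 289 bp (280 to 297) against 337 bp (332 to 343). Chromosomes differed in height and in their share of end peaks. For these 5 Mb ends no comparison within chromosomes was made, so position and the mix of chromosomes cannot be told apart.

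A lower bar for weak peaks near the ends would have brought the ratio to about 1 once weak peaks were removed, and with heights of 60 or more it was 2.52. Splitting of broad sites into several peaks would have done so after merging, and with peaks less than 1 kb apart merged it was 2.51. Both values argue against these as the whole cause. With ends of 2 Mb the ratio was 3.97, with ends of 10 Mb it was 2.12, and in the top 25% by score it was 2.33. A higher density of genes or of CpG islands near chromosome ends may account for the pattern, as a hypothesis that was not tested, since no sequence or annotation of hg18 was used here.

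The 3 segments of low height on chromosomes 4, 8 and 10 were chosen for their low heights, so the heights themselves cannot tell lower KDM2B occupancy from fewer DNA copies. Inside them, peaks scored higher than peaks of the same height, width and summit position elsewhere on the chromosome, by a log2 difference of 0.18 at the median segment, with the lowest at 0.15 on chromosome 4 (95% interval 0.14 to 0.20) and the highest at 0.21 on chromosome 10 (0.15 to 0.24), and in 96 of 105, 59 of 61 and 51 of 55 peaks on chromosomes 4, 8 and 10. Peaks of 1 segment are not independent replicates, so these counts and intervals describe the segment only. No such difference is given for other stretches of similar length, so how often they depart from the fit by as much is unknown. As deposited, the median score was lower inside all 3 segments. It was 32.2 against 35.1 on chromosome 4, 35.9 against 38.8 on chromosome 8 and 36.1 against 37.4 on chromosome 10. Lower occupancy with all else unchanged was taken to leave the score at a given height where it was. That premise rests on the formula of the score, which is not stated, so the higher score at a given height cannot decide on lower occupancy. In the 38 other 20 Mb ends, upper-quartile height was 0.965 of the rest of the chromosome at the median, which argues against a drop common to most ends. Of these ends, 3 lay below 0.75, at the end of chromosomes 11 (0.567) and 21 (0.743) and the start of chromosome 7 (0.719). The 38 ends were those left once the low segments were taken out. They cannot tell whether the composition of the segments themselves was unusual. Fewer DNA copies in OCI-Ly1 may raise the score at a given height through a lower local background. Anything else that lowers the local background would do the same. The formula of the score is not stated, and copy number was not measured here.

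The height at the threshold differed between chromosomes, from 31 on the X chromosome to 55 on chromosome 22. On the 3 chromosomes with low segments, the height at the threshold inside them was 0.953 of that outside at the median (0.949 to 0.977). It rested on 15, 16 and 11 peaks inside on chromosomes 4, 8 and 10. These include peaks whose low heights had served to find the segments, so they are not held-out values. The other chromosomes were not examined within. The threshold lies on the average log10 p, and for that column the values are consistent with a background set per chromosome. The same peaks just past the threshold had a median score of 27.8 inside (95% interval 26.5 to 29.97) against 25.4 outside (24.8 to 26.1) on chromosome 4 and 31.6 (29.2 to 33.8) against 27.6 (27.1 to 28.6) on chromosome 10, while on chromosome 8 the intervals overlapped, at 32.1 (28.8 to 33.7) against 28.7 (28.2 to 29.1). Under that hypothesis a site of a given height could be called on the X chromosome and missed on chromosome 22, so that peak numbers by chromosome would not be on 1 scale.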
